A study of Zea mays with 6 samples.

How the data were processed

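Leaves of field-grown maize (Zea mays) were profiled by RNA sequencing. The 6 libraries fall into 2 groups of 3 by the genotype label: the inbred line Q319 as wild type, and a transgenic line called L100. The labels describe the material as leaves at leaf stage 6. They do not name the transgene, so no targeted gene could be checked. Nothing in the labels says that the 3 libraries of a group came from separate plants or plots, so p-values measure only the spread between these samples.

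Per the labels, RNA was extracted with Trizol and Illumina libraries were prepared. Per the submitters' processing notes, Bowtie 0.12.2 and the genome build B73 RefGen_v3 were used. The counting tool is not given in the sources used here. The deposited tables hold 39628 gene models per library. Per the file headers, the authors' tables give an estimated count of fragments per gene, an FPKM value, 2 scaled fragment columns (a signal equal to the count times 1 factor per library) and a gene length. The lengths were multiples of 3 for 88.7% of genes and are called coding lengths here. The estimated counts deposited by the authors were whole, within 0.001, for all but 0.300% of values and were rounded to whole numbers. The deposited FPKM values and the authors' scaled signal were not tested. The authors' scaling factors entered only as an alternative scaling.

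Total counts were 8869664, 8320337 and 9922468 in wild type replicates 1 to 3 and 7536583, 7164712 and 6458248 in L100 replicates 1 to 3. A floor of 3 counts corresponds to 0.302 to 0.465 CPM in a single library. Floors and counting intervals (95%, exact binomial) cover counting error only. No pair of libraries was a repeat of the same library: the chi-square per gene between libraries of a group lay between 14.45 and 118.8, where sampling noise alone gives about 1.

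The wild type and L100 were compared with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, genes kept by filterByExpr, no block) in R 4.3.3, with Benjamini-Hochberg adjustment over 18702 tested genes and a threshold of 0.05. A second count took an absolute log2 fold change of at least 1. Values per library are CPM on TMM-scaled library sizes. Standard errors were derived as the absolute log2 fold change divided by the square root of the F statistic. Gene lists were tested with camera in limma 3.58.1 (preset correlation 0.01, Benjamini-Hochberg over 34 lists with at least 5 tested members), with camera under an estimated correlation, and with fry. Gene families were tested with camera where at least 8 members were tested.

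Gene names came from a table of RefSeq genes of the assembly Zm-B73-REFERENCE-NAM-5.0, a later build than that of the files, so it served only for names and for the order of neighbouring genes. Of the gene IDs, 18774 (47.4%) matched a record, 519 matched more than 1 record and were left unnamed, and 2492 carried an informative symbol. Only 9.36% of the tested genes had a symbol, so the lists cover a small part of each pathway. The table has no descriptions. The 38 lists had been drawn up before the data were examined, as symbols and description patterns. They were restated as symbols and synonyms after the name table, library totals and the most abundant genes had been seen, but before any test was run. They are therefore not lists fixed in full beforehand. Families were likewise formed from symbol stems in place of descriptions.

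Named genes followed a rule set before the data were examined: up to 10 rises and 10 falls among called genes with a symbol, non-overlapping libraries and a mean of at least 5 CPM; for each list described, called members or, with none called, the 2 with the highest mean; and the reference gene with the highest mean. Genes without a symbol (the 2 smallest p and the highest mean per direction) and members that passed only over their list alone were added after values were seen. The lists described with example genes were also chosen after the list results were seen.

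The test, the set test and the neighbour tests were tried on simulated data. In 5 simulations of this comparison on 18702 genes, 200 genes were changed each time and each gene had the same spread in both groups. There edgeR recovered 0.604% of 2-fold, 43.9% of 4-fold and 81.7% of 8-fold changes, and 7.21% of its calls were false. A list of 40 genes shifted by 0.5 on the log2 scale was found in all 5 simulations, and 2.6% of random lists had p under 0.05. The simulated genes varied independently of each other. The preset correlation was therefore not tried on lists whose members vary together. The neighbour tests, on 12910 placed genes, found planted segments in 20 of 20 simulations; with randomly placed calls the pair test passed in 2 of 20 and the test of uncalled neighbours in 1 of 20.

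Alternatives planned before the data were examined were DESeq2 1.42.0, limma-voom, RLE and upper quartile scaling, a looser and a stricter filter, scaling without the 20 most abundant genes, a replicate block, each library left out in turn, and camera with an estimated correlation. The planned pseudocount alternatives apply to normalized values only and were not run. Limma-voom with library weights, removal of each library's trend with coding length (loess), the authors' scaling factors and other limits for genes read in 1 line only were added after the data were seen.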

Results

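Leaf transcriptomes of the transgenic maize line L100 and its wild type, the inbred Q319, were compared at leaf stage 6, with 3 libraries per group. Total counts were 8869664, 8320337 and 9922468 in wild type replicates 1 to 3 and 7536583, 7164712 and 6458248 in L100 replicates 1 to 3. The series states as its purpose only an examination of the leaves of both lines.

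The libraries of L100 resembled each other more than those of wild type. The biological coefficient of variation was 0.2539 within L100 and 0.4955 within wild type. Wild type replicate 3 stood apart on the first principal component, which held 45.5% of the variance. Its coordinate was -116, against -35.5 and 7.16 for the other wild type libraries and 33.1 to 60.9 for L100. Without it, the coefficient within wild type was 0.436. The wild type libraries did not group together. By Pearson correlation of log2 CPM across genes, wild type replicate 1 was closest to L100 replicate 1 (0.9129). Its correlations with wild type replicates 2 and 3 were 0.8865 and 0.8602. Wild type replicate 2 was closest to L100 replicate 2 (0.9114), and wild type replicate 3 to wild type replicate 1 (0.8602).

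**Figure D1:**
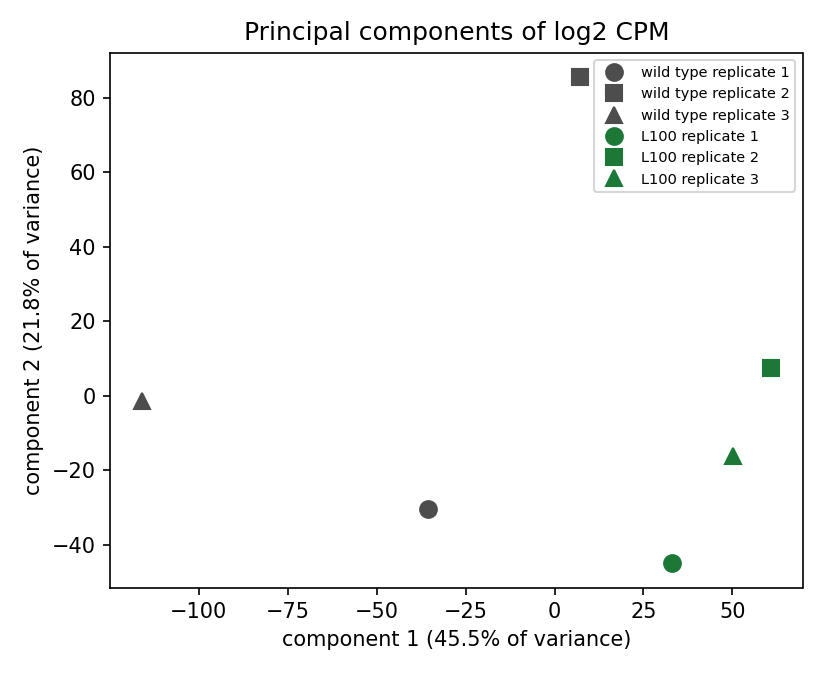
Principal components 1 (horizontal, 45.5% of variance) and 2 (vertical, 21.8%) of log2 CPM over the tested genes, 1 point per library, with grey for wild type and green for L100. The 3 L100 libraries lie at 33.1 to 60.9 on component 1, and wild type replicate 3 lies at -116.

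Of 18702 tested genes, 156 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 97 higher and 59 lower in L100. The larger number of rises was not seen with DESeq2 (279 higher, 291 lower) or with library weights in limma-voom (89 higher, 93 lower). All 156 changed at least 2-fold, and the smallest absolute log2 fold change among them was 1.503. In 117 of them 1 group had a mean under 1 CPM. The libraries of the groups did not overlap in any of the 156; over all tested genes this held for 16.2%, where chance gives 10%. Only 8 of the 156 carry a symbol, so most of the differences between the lines are known by gene ID alone. Calls of list members below are those of edgeR unless another tool is named.

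Among the named genes, cab48 (GRMZM2G120619), a chlorophyll a/b-binding protein of the light-harvesting antenna, rose from 158 ± 60.6 to 1340 ± 589 CPM (SD, n = 3 per group), a log2 fold change of 3.09 ± 0.45 (SE, edgeR adjusted p = 0.0316). Antenna proteins form a family of similar genes, so its count may include reads of close copies. The aldehyde dehydrogenase gene rf2c (GRMZM2G071021) rose from 40.7 ± 7.40 to 115 ± 9.36 CPM (log2 fold change 1.503 ± 0.253, edgeR adjusted p = 0.0463). AUX36 (GRMZM2G359924) had 2 counts over the 3 wild type libraries and 79 over the L100 libraries, a ratio of 59.7 with a 95% exact counting interval of 15.99 to 501.4 (edgeR adjusted p = 0.0298).

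The largest fall among named genes was that of igl1 (GRMZM2G046191), an indole-3-glycerol phosphate lyase that releases indole, from 16.8 ± 10.4 to 0.355 ± 0.170 CPM (log2 fold change -5.50 ± 0.77, edgeR adjusted p = 0.0268). The transcription factor gene MYB59 (GRMZM2G093789) fell from 12.4 ± 5.03 to 0.563 ± 0.240 CPM, with an edgeR adjusted p of 0.0180. The legumain-like protease gene see2b (GRMZM2G093032), first described as senescence-enhanced, fell from 197 ± 15.1 to 44.97 ± 6.34 CPM (log2 fold change -2.13 ± 0.25, edgeR adjusted p = 0.0180). The histone H2A gene his2a1 (GRMZM2G305046) fell from 9.76 ± 2.66 to 1.67 ± 0.403 CPM, with an edgeR adjusted p of 0.0352. PDIL5-1 (GRMZM2G443655), a protein disulfide isomerase-like gene, fell from 4.01 ± 0.900 to 0.355 ± 0.170 CPM, with an edgeR adjusted p of 0.0364.

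**Figure D2:**
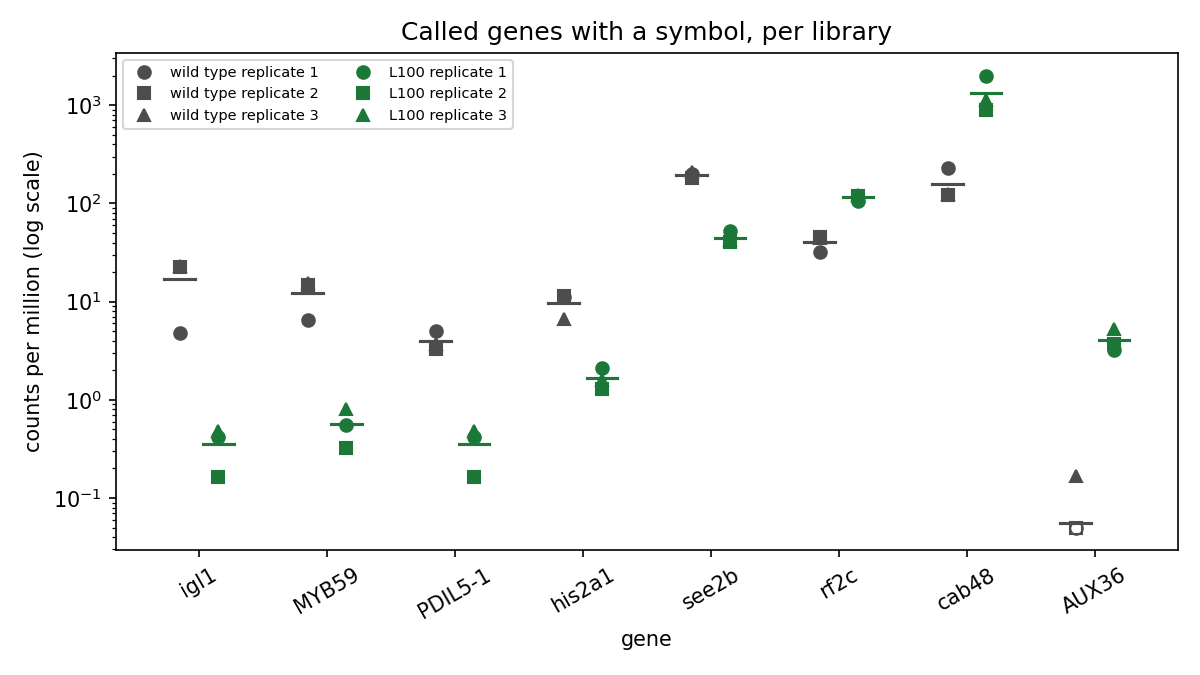
CPM on a log axis of the 8 called genes with a symbol, with 1 point per library (grey wild type, green L100) and horizontal bars at the group means; open symbols at 0.05 CPM stand for 0 counts. The groups do not overlap in any of the 8 genes, and cab48 reaches 1340 CPM on average in L100 against 158 CPM in wild type.

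The genes with the smallest p had no symbol and were picked after their values were seen. GRMZM2G463318 had 0 counts in the 3 wild type libraries and 43.2 ± 3.82 CPM in L100, at least 425.6-fold higher against a floor of 3 counts over the group (edgeR adjusted p = 0.00415). GRMZM2G029722 rose from 0.139 ± 0.0616 to 15.4 ± 0.692 CPM. GRMZM2G119675 fell from 67.1 ± 7.35 to 4.85 ± 0.579 CPM, and GRMZM2G038279 from 21.0 ± 2.84 to 1.76 ± 0.456 CPM. The most abundant called genes without a symbol were GRMZM2G070500, which rose from 10.8 ± 3.28 to 341 ± 149 CPM, and GRMZM2G068963, which fell from 362 ± 239 to 25.2 ± 7.99 CPM.

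Which genes passed the test depended on all 3 L100 libraries. Without L100 replicate 1, 6 genes were called by edgeR, and without L100 replicate 2 or 3 none were, with 1295 and 1282 genes at an unadjusted p under 0.05 against 1878 with all libraries; DESeq2 called 376 and 330 genes there and limma-voom 0. Each of the 8 named calls was lost when any 1 L100 library was left out (edgeR adjusted p 0.108 to 0.240), while their log2 fold changes stayed close to those with all libraries. They ranged from -2.24 to -2.05 for see2b, from 1.46 to 1.58 for rf2c and from 2.68 to 3.32 for cab48. In rf2c the call was also lost without each wild type library (0.0530 to 0.101). AUX36, PDIL5-1 and his2a1 were lost without wild type replicate 1 (0.0538, 0.0738 and 0.0710), his2a1 without replicate 2 (0.0530) and PDIL5-1 without replicate 3 (0.0565). Limma-voom with all libraries lost igl1 (0.259), MYB59 (0.0830), PDIL5-1 (0.0794) and his2a1 (0.0864), and with library weights igl1 (0.0967). With the stricter filter cab48 and rf2c were lost (0.0652 and 0.0803), see2b passed (0.0221) and the other 5 were not tested. All 8 were lost with the replicate number as a block in edgeR (0.0539 to 0.0977).

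Heat shock genes were mostly higher in L100, and whether they shifted as a group depended on the correlation assumed between members. The estimated correlation was 0.282 for this list, against the preset 0.01. Among the lists that passed with the preset it ranged from 0.00718 (WRKY) to 0.532 (cytosolic ribosome). Of 26 tested members, 19 were higher in L100, with a median log2 fold change of 0.825, and the list passed camera with the preset correlation (adjusted p = 0.000615) but not with an estimated one (adjusted p = 0.669 with an estimated correlation). No member passed over all genes, and 3 were higher when adjusted over the list alone. These were hsp101 (GRMZM2G360681), a disaggregating chaperone, at 14.2 ± 8.04 and 84.0 ± 27.9 CPM in wild type and L100, hsp82 (GRMZM5G833699) at 1.30 ± 1.66 and 19.1 ± 15.6 CPM, and hsp18 (GRMZM2G149647) at 1.17 ± 0.272 and 6.24 ± 4.40 CPM, named after their values were seen. The most abundant members, HSP90-1 (GRMZM2G024668) and hsp70-4 (GRMZM2G340251), had means of 596.5 ± 634.5 and 693 ± 249 CPM in wild type and 2152 ± 618 and 1240 ± 239 CPM in L100 and did not pass the test (edgeR adjusted p 0.549 and 0.486). Relative to the mean of all 6 libraries, the median of the list was -0.761, 0.308 and -0.961 in wild type replicates 1 to 3 and 0.126, 0.630 and 0.841 in L100 replicates 1 to 3. The list passed with the preset correlation without each library in turn (adjusted p 1.51e-05 to 0.0233; 0.00336 without wild type replicate 3). Its median fell to 0.330 without L100 replicate 3 and 0.540 without wild type replicate 1 and was 1.25 without wild type replicate 2.

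Photosynthesis genes were also mostly higher in L100. With all libraries, their list medians were below that of genes usually taken as stable references (log2 fold change 0.358). Of 21 tested light reaction genes 18 were higher in L100, with 1 call (cab48) and a median log2 fold change of 0.34; camera gave an adjusted p of 0.0239, and an adjusted p of 0.710 with an estimated correlation. Of 22 carbon fixation genes 18 were higher, with no call and a median of 0.295 (adjusted p = 0.0402 and, with an estimated correlation, 0.669). The C4 cycle genes pdk1 (GRMZM2G306345) and pep1 (GRMZM2G083841) were the most abundant, with 34146 ± 8601 and 24190 ± 7557 CPM in wild type against 49757 ± 5535 and 37167 ± 3929 CPM in L100 (edgeR adjusted p 0.689 and 0.664). Light reaction genes lay at a median log2 difference of -0.63 in wild type replicate 3 from the other wild type libraries. Without it neither list passed (adjusted p = 0.226 and 0.0913), and neither passed without wild type replicate 1 (0.0707 and 0.190) or L100 replicate 2 (0.0569 and 0.156). The median of the light reaction list ranged from 0.129 without wild type replicate 3 to 0.679 without wild type replicate 2 and was 0.201 without L100 replicate 1; that of the carbon fixation list was 0.190 without L100 replicate 2 and 0.195 without wild type replicate 3. With DESeq2 the carbon fixation list did not pass (adjusted p = 0.0525).

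Aquaporin genes had 13 of 17 tested members higher in L100 (median 0.63, camera adjusted p = 0.0251, and adjusted p = 0.787 with an estimated correlation). Their most abundant members, PIP1-1 (GRMZM2G174807) and pip2b (GRMZM2G092125), had means of 310 ± 253 and 172 ± 167 CPM in wild type and 492 ± 31.1 and 321 ± 71.4 CPM in L100, and neither passed the test. In wild type replicate 3 the list lay at a median log2 difference of -2.17 from the other wild type libraries, and without that library it did not pass (median 0.116, adjusted p = 0.208). It passed without each of the others, with a median of 1.23 without wild type replicate 2, and did not pass with DESeq2 (adjusted p = 0.238). Cuticle and wax genes had 13 of 15 members higher (median 0.31, adjusted p = 0.0251, and adjusted p = 0.669 with an estimated correlation), and did not pass without wild type replicate 1 or 3 (adjusted p = 0.0771 and 0.221) or with the stricter filter (0.0617). The median was 0.577 without wild type replicate 2. Their most abundant members were plt1 (GRMZM2G101958), at 56.2 ± 38.3 and 151 ± 96.0 CPM in wild type and L100, and a gene with the symbol CER1 (GRMZM2G066578), at 104 ± 73.5 and 98.6 ± 17.6 CPM. Another gene with that symbol (GRMZM2G099097) was the 1 member higher when adjusted over the list alone.

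Cytosolic ribosomal protein genes had 30 of 35 members higher in L100 (median 0.31, adjusted p = 0.0174, and adjusted p = 0.851 with an estimated correlation). Their most abundant members, rpl19 (GRMZM2G171444) and L29 (GRMZM2G028216), had means of 459 ± 118 and 313 ± 128 CPM in wild type and 611 ± 65.4 and 284 ± 50.4 CPM in L100. Among genes usually taken as stable references, 19 of 25 were higher in L100, with a median of 0.36 (adjusted p = 0.0251, and adjusted p = 0.669 with an estimated correlation). The most abundant of them, GAPC (GRMZM2G046804), had 1266 ± 84.1 CPM in wild type and 1417 ± 216 CPM in L100 (edgeR adjusted p = 0.891), and GAPC2 (GRMZM2G180625) had 866 ± 174 and 1110 ± 207 CPM. Without wild type replicate 3 both lists passed (adjusted p = 0.00336 and 0.0171). Neither passed without wild type replicate 1 (0.736 and 0.103) or L100 replicate 2 (0.153 and 0.156), and the ribosomal list did not pass without L100 replicate 3 (0.0540). The median of the ribosomal list was 0.135 without wild type replicate 1. That of the reference genes was 0.0554 without L100 replicate 2, 0.199 without wild type replicate 1 and 0.183 with the looser filter. Log2 fold changes correlated with coding length across genes, which are not independent replicates (Spearman -0.134). With that trend removed, a setting chosen after the data were seen, both lists passed (adjusted p = 0.0378 and 0.0357).

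**Figure D3:**
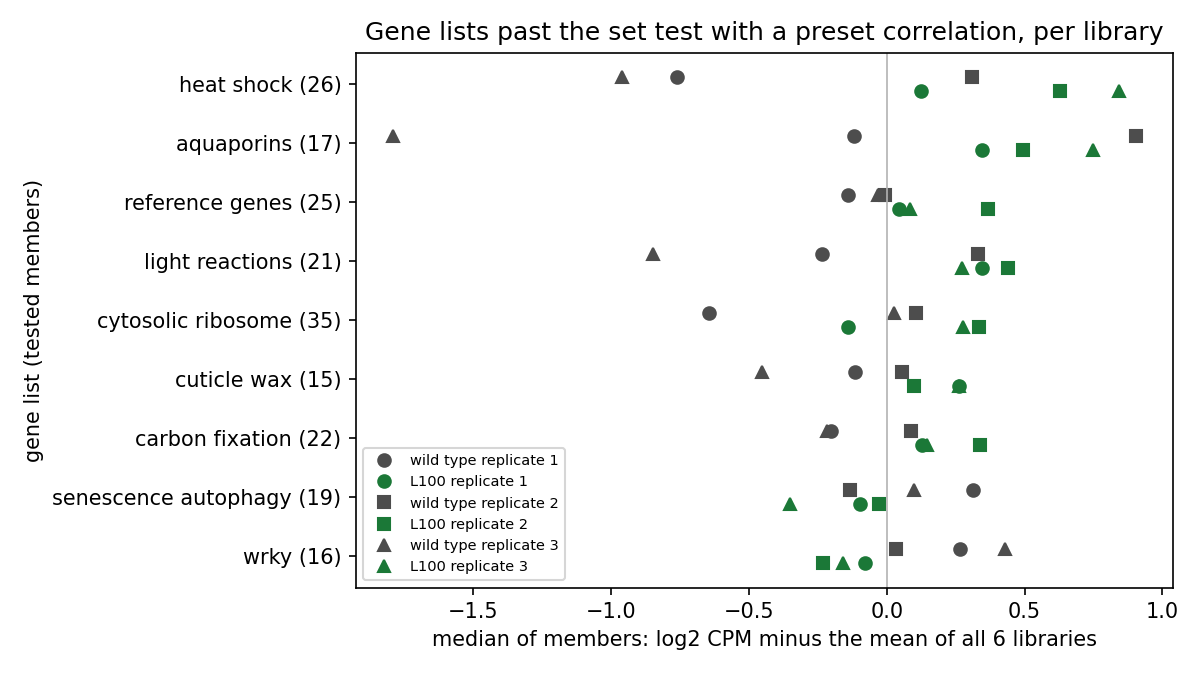
For the 9 gene lists that passed camera with the preset correlation, the horizontal axis gives each library's median over list members of log2 CPM minus the mean of all 6 libraries, with grey for wild type and green for L100. Wild type replicate 3 (grey triangles) lies at -1.79 for aquaporins and -0.848 for light reactions; for heat shock, wild type replicates 1 and 3 lie at -0.761 and -0.961 and replicate 2 at 0.308.

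Senescence and autophagy genes were mostly lower in L100, with 15 of 19 members lower, 1 call (see2b) and a median of -0.28 (adjusted p = 0.0484, and adjusted p = 0.748 with an estimated correlation). WRKY transcription factor genes had 14 of 16 members lower (median -0.45, adjusted p = 0.0402, and adjusted p = 0.669 with an estimated correlation), with no call. The most abundant WRKY members, GRMZM2G125653 and WRKY116 (GRMZM2G130854), had 23.3 ± 16.35 and 17.3 ± 6.11 CPM in wild type and 18.2 ± 11.2 and 23.7 ± 4.26 CPM in L100. The senescence list did not pass without wild type replicate 1 or L100 replicate 3 (adjusted p = 0.257 in both), with upper quartile scaling (0.0524), with the replicate number as a block (0.0775) or with the looser or stricter filter (0.101 and 0.0843). Its median was -0.453 without L100 replicate 2. With 1 library left out, the WRKY list passed only without wild type replicate 2 and had adjusted p from 0.0540 to 0.135 without each of the others. It did not pass with DESeq2 (0.177), limma-voom (0.0677, and 0.0549 with library weights) or the looser filter (0.133). By the directional test of fry, which tests each list without comparing it with other genes, none of the 34 lists passed (smallest adjusted p = 0.275). The mixed test of fry, which allows members to change in both directions, gave small p for some lists. They were 4.08e-06 for histones, 0.000442 for senescence, 0.000652 for auxin and 0.00153 for ER chaperones, not adjusted over the lists. Each of these lists held 1 called gene.

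The list of genes linked to benzoxazinoids, the indole-derived defence compounds of maize, had 1 edgeR call (igl1) and 9 of 11 members lower in L100. The call was the indole-releasing lyase gene described above, and no gene named bx was called by edgeR. The list did not pass camera (median -0.612, adjusted p = 0.114) and had an adjusted p of 0.669 with an estimated correlation. With the preset correlation it passed without wild type replicate 3 (adjusted p = 0.0171), with DESeq2 (0.00685) and with library weights in limma-voom (0.0380). When adjusted over the list alone, 4 members were lower and 1 higher. Besides igl1, these were Igl (GRMZM2G046163), at 104 ± 61.7 and 26.1 ± 7.49 CPM in wild type and L100, bx2 (GRMZM2G085661) at 12.4 ± 14.2 and 0.836 ± 0.630 CPM, bx8 (GRMZM2G085054) at 58.4 ± 14.8 and 35.3 ± 0.902 CPM, and glu1 (GRMZM2G016890) at 0.946 ± 0.619 and 3.64 ± 0.972 CPM. None of these 4 passed over all genes with all libraries in edgeR (adjusted p 0.170 to 0.382). DESeq2 called bx2 and Igl over all genes (adjusted p = 0.00375 and 0.00734) but not bx8 or glu1 (0.273 and 0.114). Without wild type replicate 1, edgeR called Igl (0.0410).

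Among 7 histone genes, his2a1 was the 1 call by edgeR. When adjusted over the list alone, the linker histone gene hon110 (GRMZM2G164020) was also lower, at 104 ± 72.6 and 26.8 ± 1.86 CPM in wild type and L100, and a gene with the symbol H1 (GRMZM2G003002) was higher, at 11.4 ± 12.5 and 84.5 ± 13.9 CPM. DESeq2 called hon110 and H1 over all genes as well (adjusted p = 0.00584 and 0.00747). The median of the list was 0.0122, its mean -0.0147 and its camera direction down (adjusted p = 0.878). Among 22 ethylene genes none passed over all genes, and the list did not pass camera (median 0.112, adjusted p = 0.619). AUX36 was the 1 call among 34 auxin genes and PDIL5-1 the 1 call among 21 ER chaperone genes. Neither list passed camera (adjusted p = 0.578 and 0.864); the ER chaperone list had a median of 0.0679 and a mean of -0.106.

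Jasmonate genes (35 tested, adjusted p = 0.328) and clock and light signalling genes (13 tested, adjusted p = 0.578) had no call. The jasmonate list, with 25 members lower in L100, passed the preset test without wild type replicate 3 (adjusted p = 0.0171) and with library weights in limma-voom (0.0419); with all libraries its adjusted p was 0.851 with an estimated correlation. The most abundant jasmonate members, lox10 (GRMZM2G015419) and TIFY24 (GRMZM2G126507), had 3149 ± 501 and 299 ± 131 CPM in wild type and 2167 ± 529 and 232 ± 47.1 CPM in L100. The clock gene gigz1a (GRMZM2G107101) had 645 ± 376 and 443 ± 54.1 CPM, and the blue-light receptor gene nph1 (GRMZM2G001457) 215 ± 107 and 129 ± 55.1 CPM. The other 22 lists had no called member, and those with at least 5 tested members did not pass camera. Of these, 4 passed the preset test upward when a library was left out. Cell wall and growth genes did so without wild type replicate 1, wild type replicate 3 or L100 replicate 2 (adjusted p = 0.0433, 0.00747 and 0.00484) and with the length trend removed (0.0479). Chloroplast biogenesis genes did so without wild type replicate 3 (0.0112), and flavonoid and redox genes without wild type replicate 2 (0.0267 and 0.0385). With all libraries their adjusted p was 0.669 to 0.862 with an estimated correlation. The lists with fewer than 5 tested members, not tested with camera, were markers of seed, root and dividing tissue with 4, 4 and 3 tested members and of pollen and anther with 0. Over 32 gene families formed from symbol stems, 1 passed camera: 11 of 12 HSP genes were higher in L100 with a median log2 fold change of 2.06 (adjusted p = 1.72e-07, and adjusted p = 0.895 with an estimated correlation). The HSP family shares members such as hsp101, hsp82 and hsp18 with the heat shock list, so it is not separate evidence.

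A further count, chosen after the data were seen, took genes with at most 3 counts over the 3 libraries of 1 line and at least 20 in each library of the other. There were 59 such genes, 26 silent in wild type and 33 silent in L100, and 56 of them were among the 156 calls. In 33 of the 59 the silent line had 0 counts. With a minimum of 10 counts in place of 20 51 were silent in wild type and 75 in L100. Such a gene can be unexpressed or can differ in sequence from the reference so that its reads were not placed. The files do not separate these cases.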

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

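Against 156 called genes, limma-voom called 155, of which 129 were among the 156. There were 156 calls with RLE, 159 with upper quartile scaling, 156 without the 20 most abundant genes and 160 with the authors' scaling factors, of which 156, 154, 156 and 156 were among the 156. None of these scalings moved the median of all genes by more than 0.05 on the log2 scale. With the looser filter 213 genes were called (153 of the 156), with library weights in limma-voom 182 (128 of them) and with the coding length trend removed 155 (150 of them); the weights, the length trend and the authors' factors were chosen after seeing the data. DESeq2 called 570 genes, 566 of them at least 2-fold, including all 156, with 48.9% higher in L100 against 62.2%. The stricter filter, which left 10610 genes to test and 50 of the 156, called 33 by either count. All 156 kept their direction wherever they were tested. Leaving out 1 library gave 0 to 222 called genes by either count. Without wild type replicates 1, 2 and 3 there were 164, 222 and 151 calls, of which 90 and 107 without replicates 1 and 3 were among the 156. Without L100 replicates 1, 2 and 3 there were 6, 0 and 0, and DESeq2 called 395, 376 and 330; the loss goes with fewer libraries in the tighter group, and its cause was not tested. The number of lists past the preset set test was 9 and ranged from 3 to 11 with 1 library left out. It was 0 with an estimated correlation, as was the number of families (1 with the preset). The replicate numbers were not taken to pair the samples in the main test, since the labels state no pairing. Deviations of same-numbered libraries from their group means correlated at 0.384, 0.348 and 0.0146 across genes. The deviations within a group are tied to each other, so these correlations are not independent and do not settle whether the samples were paired. Replicates 1 and 2 of each line correlated best with their own number, a hint from the data, while wild type replicate 3 correlated best with L100 replicate 1 (0.074). With the replicate number as a block 5 genes were called, 5 by the 2-fold count and all among the 156, and 9 lists passed. Genes at an unadjusted p under 0.05 rose in number with the block, to 2287 against 1878 without it. The senescence list was then lost (adjusted p = 0.0775) and the cell wall and growth list passed (0.0428). The 8 named calls then had adjusted p from 0.0539 to 0.0977. The planned pseudocount alternatives apply only to normalized values and were not run.

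Genes whose log2 fold change turned its sign had not passed the test: CER1 (GRMZM2G066578) gave 0.241 with limma-voom, 0.251 with the replicate block and ranged from -0.535 to 0.513 with 1 library left out (0.0274 without L100 replicate 3). With 1 library left out, L29 ranged from -0.427 to 0.129 and gigz1a from -0.807 to 0.0453, both positive without wild type replicate 3 alone. The WRKY gene GRMZM2G125653 ranged from -0.983 to 0.359 and TIFY24 from -0.554 to 0.0528, both positive without wild type replicate 1 alone. The cause was not tested. In simulations at this depth, with the same spread per gene in both groups, edgeR recovered 0.604% of 2-fold and 43.87% of 4-fold changes and DESeq2 10.27% and 75.46%. False calls were counted for edgeR alone, so whether the higher recovery of DESeq2 came with more false calls is not known. A gene that edgeR did not call may still differ 2-fold or 4-fold. In the data the coefficient of variation was 0.4955 within wild type and 0.2539 within L100, so the recovery rates may differ there.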

Other observations

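The tests of the splits of libraries, of depth, of coding length and of pairs of called genes were chosen after the result was seen, as were the criterion for genes read in 1 line only and the window of 20 places.

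Called genes lay near each other in the gene order of the later reference assembly. Of the 156 called genes 51 could be placed, among 12910 tested genes. On chromosome 3, rf2c, cab48 and see2b, 3 of the 8 named calls, lay within 68 places together with GRMZM2G021517. Pairs of successive called genes at most 1, 5, 10, 20 and 50 places apart numbered 0, 3, 5, 9 and 21, against means of 0.204, 0.993, 1.96, 3.78 and 8.85 over 10000 random placements. The permutation p was 1, 0.0747, 0.0427, 0.0088 and 0.0001, not adjusted for the 5 windows tried; the last is the smallest the permutations can give.

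Among the placed calls, 0 of the 21 pairs within 50 places were direct neighbours, which argues against adjacent tandem copies as the source of these pairs; calls that could not be placed were not covered. A candidate explanation is chromosome segments that differ between the lines, L100 and the Q319 plants used here, which predicts that uncalled genes near called ones also differ more often. Of 1663 uncalled genes within 20 places of a called gene, 266 (15.995%) had an unadjusted p under 0.05, against 8.601% of all uncalled placed genes and a 95th percentile of 10.169% around randomly placed calls (permutation p = 0.0001, the smallest possible, and 0.0007 when the calls were moved along the genome together). Shared regulation over longer distances and effects of the transgene stay open as untested, and without sequences no segment can be outlined. If such segments exist, some calls, cab48 and see2b among them, may come from the background of the line rather than from the transgene.

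Lower depth of the L100 libraries is argued against as the only source of the 59 genes read in 1 line only, since 44.1% of them were silent in wild type, the deeper group. More were silent in L100 than in wild type (33 against 26, and 75 against 51 with a minimum of 10 counts). Depth may have a part in that excess, which was not tested. The real split of the 6 libraries gave 59 such genes and the highest other split gave 1; for called genes the values were 156 and 0. In each case 1 of 10 splits, the real one, gave as many, and 10 splits are too few for a share under 0.05. By unadjusted p, the split that sets wild type replicates 1 and 3 with L100 replicate 1 against the rest had 2429 genes under 0.05, against 1878 for the real split, which points to a structure of the samples besides genotype. Whether the silent genes are unexpressed or carry a differing sequence stays open.

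In wild type replicate 3, 24.9% of all tested genes had their highest and 23.9% their lowest value of the 6 libraries. The 5 genes given here were chosen after their values were seen, because they stood apart in it; the whole clock and light signalling list lay at a median log2 difference of 0.838 from the other wild type libraries. The clock gene PRR59 stood at 67.2 CPM there and at 8.93 to 11.7 CPM in the others, gigz1b at 341.75 against 94.9 to 122.75 CPM and gigz1a at 1075 against 382 to 481 CPM. The antenna genes cab-m1 and cab-m9 stood at 383 and 786 CPM, against at least 4444 and 6159 CPM in the others.

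Harvest of wild type replicate 3 at another time of day is a candidate explanation, which predicted that conz1, a clock output gene that rises late in the day, would be highest there; conz1 stood at 16.76 CPM against 3.897 to 10.99 CPM. This is weak evidence from 1 gene, since 24.9% of all tested genes were highest in this library, and the explanation arose from the genes above. A bias by coding length is argued against, since the correlation of its deviation with coding length across genes, which are not independent replicates, was 0.0719, within the range of the other libraries (-0.127 to 0.105). Harvest times, leaf age and field position are not in the labels, so other differences between plants stay open.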
